A study of Mus musculus with 4 samples.

How the data were processed

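MicroRNAs (miRNAs) were measured on 4 single-colour miRNA arrays, 1 for each group. Per the labels, murine bone-marrow-derived mast cells (BMMC), primary mast cells grown in stem cell factor (SCF, the ligand of the receptor tyrosine kinase KIT) and interleukin 3, were profiled with and without SCF, and P815, a mouse mast cell line that carries a mutant KIT and grows without cytokines, was profiled with and without imatinib, an inhibitor of KIT. SCF was given at 100 ng per cc and imatinib at 10 nM, each for 24 h. Per the labels, total RNA was labelled with a fluorescent dye by RNA ligase. KIT is called active here in BMMC with SCF and in P815 without imatinib. This follows the treatments only: KIT activity was not measured on these arrays. Whether imatinib at this dose inhibited the mutant KIT is therefore not shown. Groups were taken from the labels, which give 1 sample per group, so no difference has a replicate error and no test or p-value was computed.

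Per the file headers, each deposited array table holds 1 mean intensity per probe, made from foreground medians on a linear scale, with no background column. The array maker, the scanner and the number of spots per probe are not given in the sources used here. Each array had 1406 probes: 785 perfect-match miRNA probes, 604 mismatch probes and 17 control probes. Of the miRNA probes, 107 were named for viral or worm miRNAs. The largest intensity on any array was 44147, and no saturation flag was given. The median intensity of the miRNA probes was 504.0 in BMMC without SCF, 356.8 in BMMC with SCF, 251.8 in P815 without imatinib and 232.2 in P815 with imatinib. The median of the mismatch probes, a measure of background, was 295.8, 277.2, 203.0 and 180.0 in the same order. The number of arrays limits the precision.

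The authors' processed table of the series was set against the array intensities. Its values equalled the array intensity minus that array's median mismatch probe, with a residual of at most 5e-06, and were left blank where the intensity was under 1.5 times that median, a rule that matched all 802 entries on each array. The values are linear intensities, not ratios. The 2 treated arrays were further multiplied by 1 factor each, 0.834 for BMMC with SCF and 0.628 for P815 with imatinib, which made the medians of the listed values equal within a cell type: 519.2 in both BMMC columns and 268.1 in both P815 columns. The cell types were scaled separately. The labels do not state how these values were made. No column was left without a sample. A probe that the authors left blank on an array is called not listed there. Where these values were compared, a blank on 1 of the 2 arrays was set at that array's lowest possible listed value, and no difference was taken where the listed side lay below that limit.

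The main values were computed from the array intensities. The normexp background correction of limma 3.58.1 (R 4.3.3) was applied to all probes with an offset of 50. After log2 transformation, quantile normalization was run over the 4 arrays on the perfect-match miRNA probes. Mismatch and control probes were then placed on the same scale through each array's own intensity map. A miRNA's probe was the one named for mouse, otherwise the human-named one, otherwise the rat-named one, where a mouse gene of that name is in the reference gene table of assembly GRCm38.p6, which was used for names only. The plan called for probes of mouse miRNAs where a species is named, and was read this way because the array carries many conserved miRNAs only under their human names. This gave 389 mouse miRNAs, 167 with a mouse-named, 206 with a human-named and 16 with a rat-named probe. A gene was matched for 379, and 10 mouse-named probes had no gene of that name in the table. Hybridization may not separate near-identical family members, such as those of let-7, miR-17 and miR-20, miR-103 and miR-107, and miR-467, so differences within these families are uncertain. Probes of the same miRNA named for different species gave differences apart by a median of 0.14 on the log2 scale for SCF (59 pairs), 0.17 for imatinib (34 pairs) and 0.18 for P815 against BMMC (39 pairs). The 95th percentile of these gaps was 0.47, 1.09 and 1.02, so on some miRNAs the choice of probe alone moved a difference by more than 2-fold.

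A miRNA entered a comparison if it was listed on at least 1 of the 2 arrays compared, and counts were taken at a difference of at least 2-fold. Where it was listed on 1 array only, the difference is open-ended. A bound was then computed as the listed value against the higher of the lowest normalized value among listed probes on the other array and the probe's own value there, and is written as "at least N-fold". Virus and worm probes, most of which have no matching RNA known in these cells, gave the background of each count in the same way. A worm miR-34 probe shares its family name with mouse miRNAs and was listed on all 4 arrays, so it may bind a mouse miRNA. Named miRNAs were set by a rule fixed before the data were examined: the 10 highest and 10 lowest differences of each treatment, any miRNA 2-fold apart in the same KIT direction in both systems, the 5 highest and 5 lowest between the cell types, miR-381 and miR-539, and up to 4 members of each list with the largest differences. The 14 lists and 8 marker lists of other cell types were fixed at the same time, except that an older name of the same number for the same gene was also matched, and star forms were left out of lists. A list with at least 3 listed members was described by its median and by the median's percentile among 10000 random lists matched on deciles of mean expression. The percentile is not given where most members were listed only on the array that the sign of the median favours, since the random lists were not matched on this. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.

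The normalization, the calls and the percentiles were tested on simulated data. Known changes were put into brighter probes of arrays built from the mean intensities of each cell type with an assumed noise. The BMMC simulation (224 miRNAs) called 18 of 20 at a true 4-fold and 16 of 20 at a true 2.5-fold difference, with 1 call among 184 unchanged ones. The P815 simulation (172 miRNAs) called 19 of 20 and 12 of 20, with 2 calls among 132 unchanged ones. The median estimate for a true log2 difference of 2 was 1.59 in the BMMC and 1.76 in the P815 simulation, so differences were understated. The assumed noise was smaller than the spread of virus and worm probes on the real arrays (SD 0.31 with SCF and 0.64 with imatinib). Of the listed ones, 1 of 60 and 5 of 41 passed 2-fold. The simulated rates of false calls therefore do not carry over to these arrays.

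Alternatives to the scaling between arrays, the background correction, the detection rule, the threshold, the probe set and the source of values were fixed before the data were examined. Alternatives limited to mouse-named probes, to values above the 95th percentile of virus and worm probes, to probes at least 1.5 times their mismatch probe, to the authors' values with medians matched over shared probes, and to the authors' values with their scale factor, their subtraction or both left out were chosen after seeing the data. A difference was read as moved when it shifted by more than the SD of the virus and worm probes' differences in that comparison, a list median by more than the SD of its random lists, a correlation by more than its bootstrap SD over miRNAs (1000 draws), and a count by more than 1.5 times.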

Results

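Expression of 389 mouse miRNAs was measured on 4 arrays, 1 each for BMMC without SCF, BMMC with SCF, P815 without imatinib and P815 with imatinib. The number of these miRNAs listed by the authors was 254 in BMMC without SCF, 175 in BMMC with SCF, 153 in P815 without imatinib and 169 in P815 with imatinib. Of the 107 virus and worm probes, 60, 35, 32 and 39 were listed in the same order. There were no replicates, so a difference describes a pair of arrays, and higher and lower are used without a test throughout. Across the 785 miRNA probes, log2 intensities correlated at r = 0.98 between the BMMC arrays and at r = 0.92 between the P815 arrays, against 0.84 between P815 without imatinib and BMMC with SCF.

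The first comparison asked which miRNAs differ when KIT is stimulated by its ligand in primary mast cells. Few did. Of 256 listed miRNAs, 5 were at least 2-fold higher in BMMC with SCF and 0 were at least 2-fold lower. The 5 were miR-471 (3.84-fold), miR-7* (2.33-fold), miR-698 (2.31-fold), miR-302b (2.16-fold) and miR-495, which was not listed without SCF and was at least 1.49-fold higher. miR-302b and miR-302a (1.88-fold) belong to a cluster known from pluripotent cells, and miR-495 and miR-543 (at least 1.64-fold higher, not listed without SCF) to the Dlk1-Dio3 imprinted cluster. The remaining highest values were those of miR-505 (1.88-fold), miR-568 (1.81-fold) and miR-145 (1.67-fold). The mismatch probe of miR-568 was brighter than the miR-568 probe itself on every array.

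The lowest values with SCF were small. miR-10b differed by -0.64 on the log2 scale and was not listed with SCF, which bounds its difference at only 1.11-fold. The log2 difference was -0.59 for miR-696, -0.56 for miR-346, -0.54 for miR-129-5p, -0.50 for miR-106a (0.04 on its human-named probe) and -0.49 for let-7d* and miR-292-5p. miR-297, miR-487b and miR-324-3p lay at -0.44, -0.42 and -0.42, and miR-487b was not listed with SCF.

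Probes named for virus and worm miRNAs had a similar spread of SCF differences. The SD of the log2 difference was 0.32 over the mouse miRNAs and 0.31 over the 60 listed virus and worm probes, of which 1 was 2-fold higher (1.67%, against 1.95% of the mouse miRNAs). Before scaling, the median miRNA probe was lower with SCF by a log2 difference of -0.60, and differences are given relative to that shift. Without scaling between arrays, where the median listed miRNA lay at -0.61, 1 miRNA was 2-fold higher and 15 were 2-fold lower. In the authors' processed values, with a median of -0.90, 1 was higher and 105 were lower.

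miRNA lists moved little with SCF. In the miR-17-92 and paralogous clusters, which promote proliferation, 14 listed members had a median log2 difference of -0.12 (percentile 6.53) and 0 were 2-fold apart, with miR-106a lowest and miR-106b highest, at 0.30. In the Dlk1-Dio3 cluster, 25 listed members, 16 of them listed only without SCF, had a median of -0.08, and 1, miR-495, was 2-fold higher. miR-221 and miR-222, known repressors of KIT, differed by 0.34 and 0.21, and their median turned negative without scaling and in the authors' processed values. The median was 0.23 for the miR-30 family (percentile 93.4, with miR-30b at 0.37), 0.08 for the haematopoietic list (percentile 80.5, with miR-142-3p at 0.39 and, on its human-named probe, at -0.36) and 0.02 for the activation-induced list (percentile 64.3, with miR-212 at -0.23 and miR-146a at 0.22), and the sign of each of these 3 medians turned without scaling and in the authors' processed values. let-7 and miR-98 (percentile 71.3) and the miR-23, miR-24 and miR-27 clusters (percentile 57.3) had medians of 0.00. The miR-15 and miR-16 family (-0.01, percentile 47.6), the miR-29 family (-0.05, percentile 30.1), the miR-34 family (0.00, percentile 59.1), the miR-181 family (0.08, percentile 73.6) and the Sfmbt2 intronic cluster (-0.03, percentile 55.7) had no member 2-fold apart, and each of these 5 medians changed sign under at least 1 other scaling.

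The next comparison asked what follows when the mutant line is treated with a KIT inhibitor. The P815 arrays differed more than the BMMC arrays, in virus and worm probes too. With imatinib the SD of the log2 difference was 0.82 over the mouse miRNAs and 0.64 over the virus and worm probes. With SCF these were 0.32 and 0.31. Of 185 listed miRNAs, 16 were at least 2-fold higher and 14 at least 2-fold lower with imatinib. The highest was miR-689 (6.35-fold), for which the reference table holds no gene. It was followed by let-7d* (at least 4.49-fold), miR-698 (3.55-fold), miR-346 (3.26-fold) and miR-485-3p, a Dlk1-Dio3 miRNA (at least 2.86-fold). The others among the 10 highest were not listed without imatinib and have only bounds: at least 1.73-fold for miR-328, 1.53-fold for miR-294, 1.48-fold for miR-615, 1.30-fold for miR-211 and 1.23-fold for miR-18a*. miR-294 belongs to a cluster typical of embryonic stem cells. Of the 16 higher miRNAs, 5 were listed on both arrays, and 7 stayed at 2-fold when every difference was taken at its bound.

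The miRNAs lower with imatinib were mostly measured on both arrays. Of the 14, 11 were listed on both, and 12 stayed at 2-fold when every difference was taken at its bound. miR-568 was 4.60-fold lower and miR-703 was 4.50-fold lower. miR-466 (3.33-fold) and miR-467a (2.24-fold) carry names of a large family of which many members lie in an intron of Sfmbt2. miR-452* was 2.62-fold, miR-713 2.61-fold and miR-574 2.42-fold lower. miR-27a, which is processed from one transcript with miR-23a and miR-24, was 2.21-fold lower, and miR-19b, a member of the miR-17-92 cluster, was 2.08-fold lower. miR-363* and miR-1, a muscle miRNA, were not listed with imatinib and were at least 1.94-fold and at least 2.03-fold lower. A rat-named miR-1 probe, which was listed, differed by only -0.01, so the miR-1 difference was not seen on it. Likewise a human-named miR-211 probe differed by 0.07 with imatinib, and one for miR-485-3p by 1.52.

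Mismatch probes moved with the higher miRNAs. Of the 16, 11 had a mismatch probe, and these mismatch probes were higher with imatinib by a median log2 difference of 1.51, against 1.61 for the matched probes. For the 8 lower miRNAs with a mismatch probe, the mismatch probes were lower by a median of 0.32, against 1.23. Several of these mismatch probes were already near background without imatinib. Among the 41 listed virus and worm probes, 5 were 2-fold higher (12.2%, against 8.65% of the mouse miRNAs) and 0 were 2-fold lower, against 7.57%. The split between higher and lower depended on the scaling: it was 38 to 3 with median centring, where the median listed miRNA moved from -0.22 to 0.37, 37 to 3 without scaling, and 14 to 23 in the authors' processed values.

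**Figure D1:**
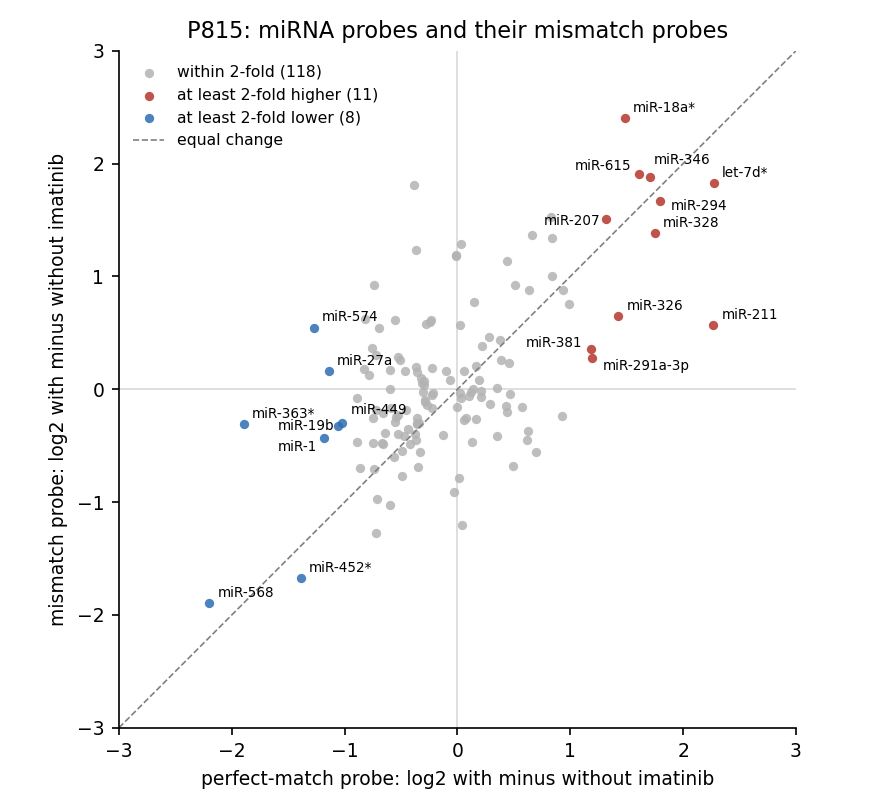
Log2 difference with minus without imatinib in P815 for the miRNA probes that have a mismatch probe (x axis) and for those mismatch probes (y axis), 1 point per listed mouse miRNA, with 1 array per group. Of the 11 probes at least 2-fold higher, 7 have a mismatch probe that is also at least 2-fold higher, while 2 of the 8 lower probes have a mismatch probe that is 2-fold lower.

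By list, 8 of the 13 listed Dlk1-Dio3 members were higher with imatinib, with a median log2 difference of 0.06 (percentile 83.0) that turned negative with no detection filter and with detection on both arrays. In that cluster 2 members were 2-fold higher, miR-485-3p and miR-381. miR-679 lay at -0.87. In the miR-17-92 clusters the median over 12 listed members was -0.32 (percentile 19.1), with 10 members below 0 and 1, miR-19b, 2-fold lower. The miR-23, miR-24 and miR-27 clusters had a median of -0.53 (percentile 10.8), with all 5 members below 0 and miR-27a 2-fold lower. The medians of the miR-29 family (-0.31, percentile 36.4), the miR-15 and miR-16 family (-0.29, percentile 41.6) and the activation-induced list (-0.29, percentile 39.2, with miR-155 at -0.74) included no member 2-fold apart. The medians of these last 5 lists turned above 0 with median centring and without scaling. The miR-34 family had a median of -0.66 (with miR-34c at -0.74), but 2 of its 3 members were listed only without imatinib, which favours a negative value. The Sfmbt2 cluster had one of -0.41 (percentile 13.9), with 2 of 7 members, miR-467a and miR-669c, 2-fold lower. The haematopoietic list (0.24, percentile 89.8, with miR-191 at 0.64) and the let-7 family (0.02, percentile 78.5, with let-7g at -0.89) had no member 2-fold apart, and both medians turned negative with cyclic loess. The miR-30 family had a median of 0.21 (percentile 50.1, with miR-30d at 0.69). miR-221 and miR-222 lay at -0.36 and -0.37 and turned above 0 with median centring and without scaling, and the 2 listed miR-181 members at 0.35 and 0.17.

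**Figure D2:**
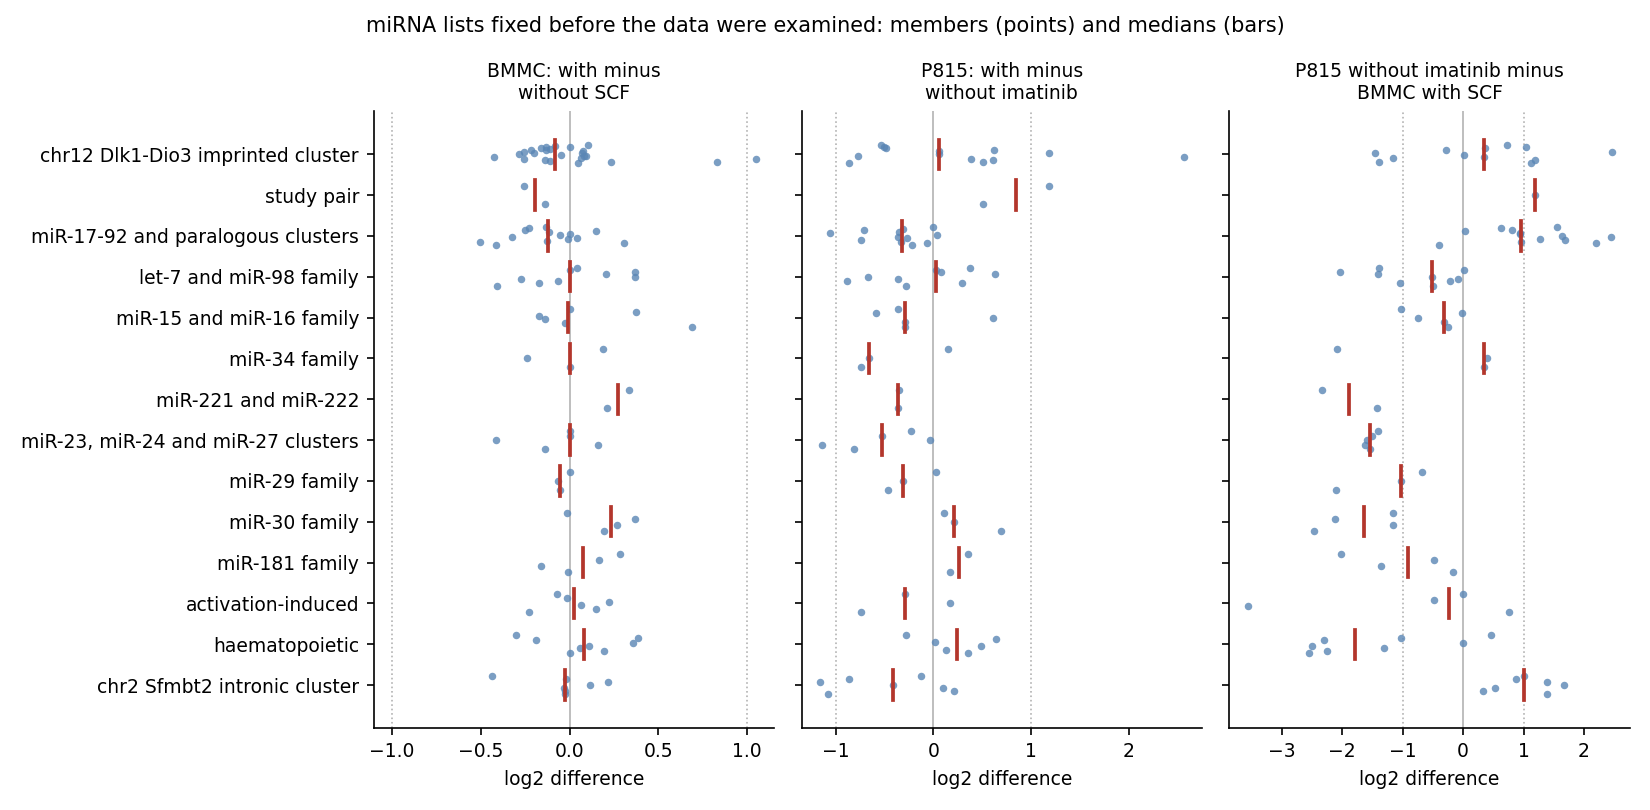
Log2 differences of the listed members (points) and their median (bar) for each of the 14 miRNA lists, in BMMC with minus without SCF, P815 with minus without imatinib, and P815 without imatinib minus BMMC with SCF. Each value is from 1 array per group and dotted lines mark 2-fold. In the last panel the haematopoietic list has a median of -1.78, with 6 of 8 members at least 2-fold lower.

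The study's main question was which miRNAs follow KIT activity in both systems. Of 177 miRNAs listed in both, 0 were at least 2-fold lower and 0 were at least 2-fold higher with KIT active in both. With 0 lower and 3 higher in BMMC, and 15 lower and 12 higher in P815, independent lists would share 0.00 and 0.20. miR-568 was higher with KIT active in both systems, by 1.81-fold and 4.60-fold, and passed 2-fold in both with median centring, 75th percentile scaling, quantile normalization within each cell type, cyclic loess and plain background subtraction. Its mismatch probe went the same way in both systems, with log2 differences of 0.65 with SCF and -1.90 with imatinib, against 0.85 and -2.20 for the matched probe. Over all mouse miRNAs with a mismatch probe, the median mismatch difference was 0.40 with SCF and -0.03 with imatinib. The positive sign with SCF was therefore not particular to miR-568. Its mismatch probe nevertheless rose in intensity with SCF, from 3490.0 to 4310.0, while the mismatch median fell from 295.8 to 277.2. With imatinib the miR-568 mismatch probe fell from 2931.0 to 1483.0. It was brighter than the matched probe on every array, so the miR-568 signal cannot be assigned to a matched sequence. miR-698 went opposite ways, higher with SCF and higher with imatinib. Across these miRNAs, which are not independent replicates, the KIT effects correlated at r = 0.20 and rho = 0.27, and r was 0.27 without miR-471 and miR-7*. Over the 41 virus and worm probes r was 0.15 and rho 0.34. In the authors' processed values, 11 miRNAs were at least 2-fold lower with KIT active in both systems. In those values 105 miRNAs were 2-fold lower with SCF and 14 were 2-fold higher with imatinib. Independent lists of these sizes would also share members, and that number was not computed. miR-381 and miR-539 were not among the 11.

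**Figure D3:**
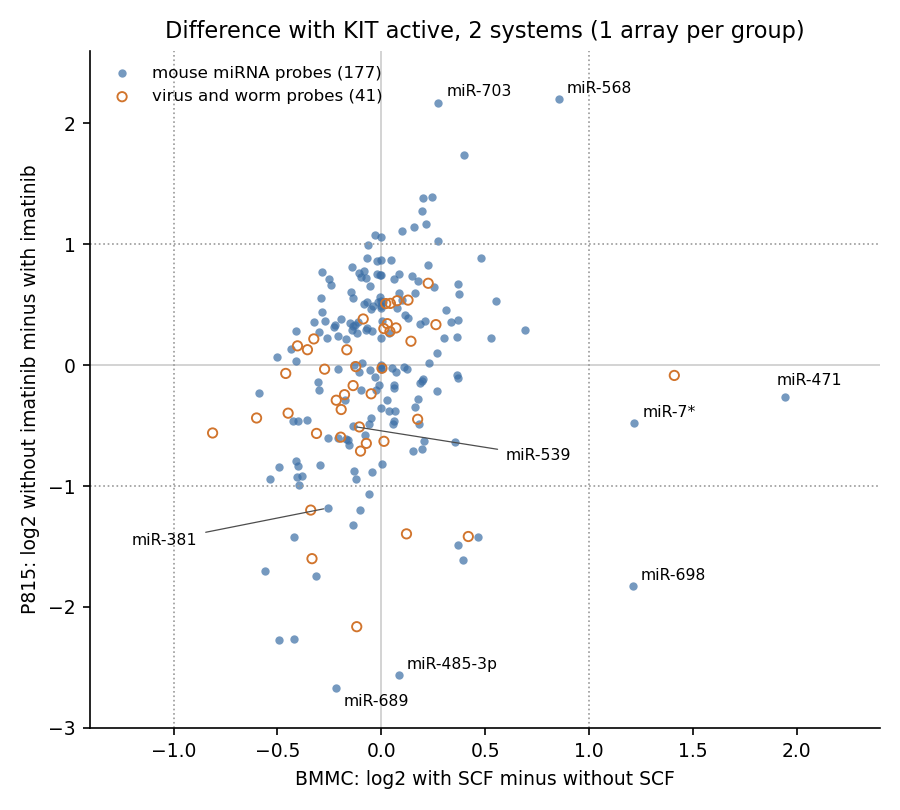
Log2 difference with KIT active in BMMC (x axis, with SCF minus without) and in P815 (y axis, without imatinib minus with), for 177 mouse miRNA probes and 41 virus and worm probes, with 1 array per group. Dotted lines mark 2-fold. The corners for 2-fold in the same direction in both systems are empty, and miR-698 lies past 2-fold in opposite directions.

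miR-381 and miR-539, which lie in the Dlk1-Dio3 cluster, were named by the study from these same samples, so their direction here is not independent evidence. Both were lower with KIT active in both systems, by unequal amounts. Of the 177 miRNAs listed in both, 86 (48.6%) had the same sign in both systems, in either direction. let-7d* (-0.49 with SCF and 2.27 with imatinib) and miR-346 (-0.56 and 1.70) went the way of the pair by more. miR-381 and miR-539 kept their signs under the 8 alternatives of scaling, background and source of values. Those alternatives reuse the same arrays, so they do not measure array noise. Without scaling and in the authors' processed values most miRNAs were lower with SCF (medians -0.61 and -0.90), so a negative sign there was usual. With SCF both differences lay within the SD of the virus and worm probes (0.31). A rat-named probe for miR-381, not listed on any array, differed by 0.02 with SCF and by 0.18 with imatinib, so the sign with SCF was not the same on that probe. miR-381 differed by -0.26 on the log2 scale with SCF, where it was not listed, and by 1.18 with imatinib, a difference bounded at 1.49-fold because it was not listed without imatinib. miR-539 was listed on all 4 arrays and differed by -0.14 with SCF and by 0.51 with imatinib. Their mismatch probes differed by 1.09 and 1.30 with SCF, the opposite way to the matched probes and by more, and by 0.35 and 0.92 with imatinib. Over all mouse miRNAs with a mismatch probe, the median mismatch difference was 0.40 with SCF (186 miRNAs) and -0.03 with imatinib (137 miRNAs). Only the positive sign with SCF was therefore usual, since both values lay above that median. In intensity these mismatch probes rose with SCF, from 266.5 to 320.5 for miR-381 and from 268.5 to 371.0 for miR-539. The mismatch median fell from 295.8 to 277.2. With SCF the matched probes read 415.8 and 467.8, not far above their mismatch probes, so the small SCF differences of the pair are uncertain. In the authors' processed values, miR-539 differed by -1.51 with SCF and by 0.94 with imatinib.

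The 2 cell types with active KIT differed far more than either treatment. Of 196 listed miRNAs, 38 were at least 2-fold higher and 59 at least 2-fold lower in P815 without imatinib than in BMMC with SCF, and 34 and 37 stayed so at their bound. miR-193b was at least 4.85-fold higher in P815. miR-431, a Dlk1-Dio3 miRNA, was 5.48-fold higher, miR-20b 5.43-fold and miR-106a 4.58-fold, both of the miR-106a cluster, and miR-574 4.16-fold. Other probes gave smaller differences, with log2 values of 0.40 for miR-431 on a human-named probe that was not listed, 1.39 and 1.42 for miR-20b, and 1.53 for miR-106a. The lowest in P815 were miR-146b (at least 11.4-fold), an inhibitor of innate immune signalling, miR-210 (7.36-fold), the main miRNA induced by hypoxia, miR-10a (at least 6.32-fold), which lies in the Hoxb locus, miR-107 (5.88-fold) and miR-720 (at least 3.99-fold), for which the reference table holds no gene. None of these 10 changed sign under the 6 alternatives of scaling and background that allow the comparison. They were picked as the largest differences on the same arrays, so this was favoured in advance. In P815 without imatinib the miR-210 probe (470.0) was hardly brighter than its mismatch probe (462.5), so its exact fold is uncertain. Of the 40 listed virus and worm probes, 5 were 2-fold higher and 6 lower (27.5%, against 49.5% of the mouse miRNAs). The split of 38 to 59 became 7 to 77 with median centring, 23 to 56 with cyclic loess and 2 to 113 without scaling, where the median listed miRNA lay at -1.30.

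The haematopoietic list, of miRNAs abundant in myeloid and mast cells, was lower in P815, with 6 of 8 listed members at least 2-fold lower and a median of -1.78 (percentile 0.31). miR-107, miR-26a (-2.50), miR-223 (at least 1.45-fold, not listed in P815) and miR-103 (-2.26) were its lowest members. The 4 listed members of the miR-30 family were all 2-fold lower, with a median of -1.64 (percentile 1.97), and so were the 5 members of the miR-23, miR-24 and miR-27 clusters, with a median of -1.55 (percentile 3.57). miR-221 and miR-222 were 5.06-fold and 2.70-fold lower. The medians of the let-7 family (-0.52, 4 of 9 members 2-fold lower, percentile 26.3), the miR-29 family (-1.02, percentile 14.8), the miR-181 family (-0.92, percentile 20.5), the miR-15 and miR-16 family (-0.31, percentile 36.2) and the activation-induced list (-0.24, percentile 50.4) were below 0 as well, and none of these signs turned under another scaling. In the miR-30, miR-181 and activation-induced lists, 2 of 4 members each were listed only in BMMC, which favours a negative value.

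In the other direction, 12 of 13 listed members of the miR-17-92 and paralogous clusters had higher values in P815, 6 of them at least 2-fold, with a median of 0.95 (percentile 98.95) that turned negative only without scaling. miR-92 (3.22-fold) and miR-20a (3.12-fold) followed miR-20b and miR-106a. In the Sfmbt2 cluster, 4 of 7 members were 2-fold higher, led by miR-467b (3.18-fold), with a median of 1.002 (percentile 93.8), which also turned negative without scaling. The miR-34 family had a median of 0.34 (percentile 51.9), with miR-34a 4.24-fold lower, and turned negative without scaling. The Dlk1-Dio3 list went both ways, with 4 of 12 members at least 2-fold higher, 3 at least 2-fold lower and a median of 0.35 (percentile 89.5), which turned negative with median centring and without scaling.

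**Figure D4:**
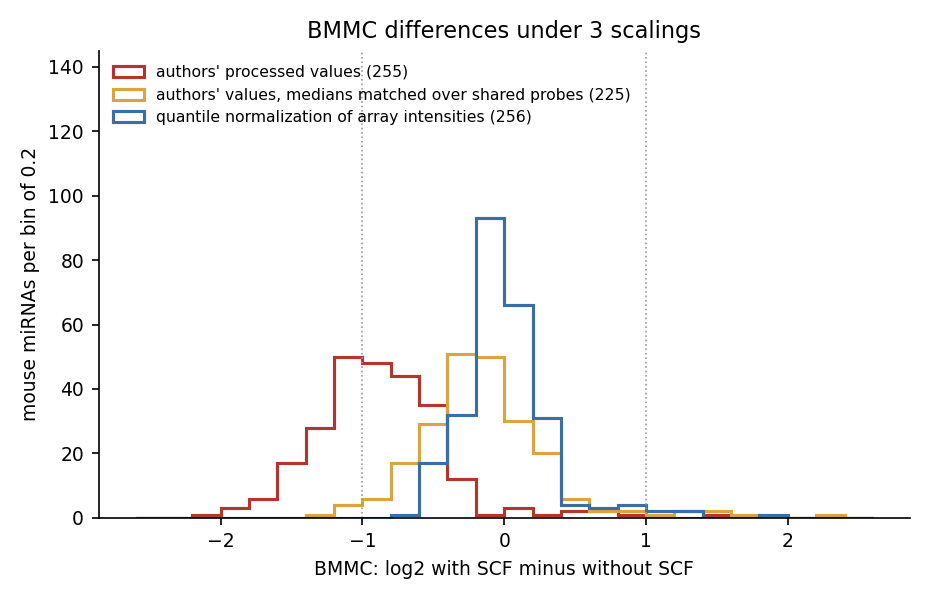
Number of mouse miRNAs (y axis, bins of 0.2) by log2 difference with minus without SCF in BMMC (x axis), 1 array per group, under 3 treatments of the same arrays. The authors' values and the quantile-normalized values differ in the background step as well as in the scaling. The authors' processed values put 105 miRNAs at or below 2-fold lower, the same values with medians matched over shared probes put 5 there, and quantile normalization puts 0 there.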

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

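The tests on mismatch probes, on the authors' scale factor and subtraction, and on how many miRNAs stay past 2-fold under other scalings were chosen only after the results were seen. The other scalings were themselves planned. Matching the medians over shared probes was chosen after seeing the data but before its own result was computed.

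In the authors' processed values, 105 miRNAs were at least 2-fold lower with SCF in BMMC and 1 was higher, against 0 and 5 after quantile normalization. With the authors' scale factor left out and their subtraction kept, 46 were lower. With the subtraction of the mismatch median left out and the factor kept, 35 were lower, and with both left out, 2 were. Neither step alone accounts for the 105, and neither is excluded as a part of it. The authors' medians were equal over 483 listed probes without SCF and 321 with SCF, and over the 317 probes that both arrays list they were 929.0 and 542.6. Matching the medians over those shared probes left 5 lower, but this centres the shared probes, so it does not decide whether medians matched over unlike sets of probes were the cause. Control spots were dimmer with SCF too: the ratio of intensities with over without SCF was 0.674 to 0.753 over the Lambda spikes, 0.50 for Bio B and 0.87 for Bio C. The amounts of spike added are not given, so a lower level of most miRNAs with SCF, which scaling to equal medians would remove, stays open.

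With imatinib, 16 miRNAs were at least 2-fold higher in P815. Among scalings that move the median listed miRNA by at most 0.1 on the log2 scale, the choice is argued against as the whole cause. Under each of the 3 other scalings of this kind, 11 of the 16 stayed at least 2-fold higher. This covers only scalings close to the main one. Median centring and no scaling raise nearly all miRNAs and so could not end a higher call. In the authors' processed values 8 of the 16 stayed. Their median also lay within that limit (-0.25 against -0.22), but they differ in the background step as well as the scaling. Binding that does not need a matched sequence is consistent with the values: the mismatch probes of the 11 members that have one were higher by a median log2 difference of 1.51 (quartiles 0.61 and 1.85), against 1.61 for the matched probes. The mismatch probes of 4 members differed by less: 0.28 for miR-291a-3p, 0.35 for miR-381, 0.57 for miR-211 and 0.65 for miR-326. A second probe differed by 1.57 for miR-326, by 0.07 for miR-211 and, not listed, by 0.18 for miR-381. An effect of imatinib stays open and untested.

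With imatinib, 14 miRNAs were at least 2-fold lower in P815. For the 8 with a mismatch probe, those mismatch probes were lower by a median of 0.32 (quartiles 0.18 and 0.74), against 1.23 for the matched probes. This does not decide whether binding that does not need a matched sequence was the cause. Without imatinib, mismatch probes of miR-574 (234.0), miR-363* (196.0), miR-1 (174.0) and miR-27a (170.0) were near the mismatch median (203.0) and had little room to fall. For miR-574 and miR-27a the matched probes read 6221.5 and 768.5, so most of that signal needed a matched sequence. The brighter mismatch probes of miR-568 (2931.0) and miR-452* (951.0) were also 2-fold lower. The choice of scaling between arrays stays open. Of the 14, 9 stayed at least 2-fold lower with 75th percentile scaling, 10 with quantile normalization within each cell type and 10 with cyclic loess, and 7 under all of these 3. With median centring and without scaling 3 stayed, but these raise nearly all miRNAs. In the authors' processed values 12 stayed. An effect of imatinib stays open and untested.

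miR-698 drew attention because its KIT effects were opposite: it was higher with SCF in BMMC by a log2 difference of 1.21, and the difference without minus with imatinib in P815 was -1.83. This opposition was not tested. It has no mismatch probe on the array.

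Signal was present in probes outside the main measurement. Virus and worm probes at or above 1.5 times the mismatch median numbered 60 of 107 in BMMC without SCF, 35 in BMMC with SCF, 32 in P815 without imatinib and 39 in P815 with imatinib. The control spot named Bio C differed by 1.93 on the log2 scale with minus without imatinib, with intensities of 23761 and 3136 (7.58-fold), and Bio B by 0.47.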

How the results depend on the processing

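The alternatives marked as chosen after seeing the data were the ones not planned. No paired analysis was possible because the groups hold 1 array each. The alternative that takes a median over replicate spots or probes was not run, since the files give 1 mean per probe and 1 probe was used per miRNA. The P815 against BMMC comparison was not run on the authors' values or with quantile normalization within each cell type, where the cell types are scaled separately. Of the alternative values of the miRNAs named for the highest and lowest differences and of miR-381 and miR-539, 312 stayed within the spread of virus and worm probes, 99 moved further and 0 changed sign. Most of these miRNAs were picked as the largest differences on the same arrays, so an unchanged sign was favoured in advance. Another probe of the same miRNA was not among these alternatives. On one, the sign with SCF turned for miR-106a (-0.50 to 0.04) and miR-381 (-0.26 to 0.02). Members named only for their list are not in these counts, and the signs of some of them turned, as for miR-221 and miR-222 with imatinib and for miR-122a. Of the alternative list medians, 275 stayed within the spread of random lists, 102 moved and 2 with a main median of at least 2-fold changed sign: in P815 against BMMC, the Sfmbt2 cluster to -0.28 without scaling, and the stromal markers to 0.32 with no detection filter. Signal over background limits the values: the median miRNA probe was under 2 times the median mismatch probe on each array.

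The numbers below are counts of miRNAs 2-fold higher and lower, and except where construction is named, the cause was not tested. Median centring gave 8 higher with SCF, 38 higher and 3 lower with imatinib, and 1 higher with KIT active in both systems. That 1, miR-568, was also the count with 75th percentile scaling, cyclic loess and quantile normalization within each cell type, and the last 2 gave 8 higher with SCF. Without scaling, 1 was higher and 15 lower with SCF, 37 higher and 3 lower with imatinib, and 6 lower with KIT active in both. No background correction gave 3 higher with SCF. Plain background subtraction, which widens differences of dim probes, gave 12 higher and 5 lower with SCF, 31 higher and 31 lower with imatinib, and 2 lower and 1 higher with KIT active in both. The authors' processed values gave 1 higher and 105 lower with SCF, 23 lower with imatinib and 11 lower with KIT active in both; with medians matched over shared probes (chosen after seeing the data) they gave 5 lower with SCF and 44 lower with imatinib. Also chosen after seeing the data, the authors' values without their scale factor gave 2 higher and 46 lower with SCF, their factor without the subtraction gave 1 higher and 35 lower, and neither step gave 1 higher and 2 lower.

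By construction, other thresholds and filters change the counts. At 1.5-fold, 12 were higher and 2 lower with SCF, 37 higher and 44 lower with imatinib, and 1 higher with KIT active in both. At 3-fold, 1 was higher with SCF, 9 higher and 4 lower with imatinib, and 37 differed between the cell types. Detection on both arrays left 5 higher with imatinib and 60 that differed between the cell types. Probes of all species gave 10 higher with SCF and 38 higher with imatinib. Chosen after seeing the data, mouse-named probes alone gave 3 higher with SCF, 6 lower with imatinib and 38 that differed between the cell types. Detection above the 95th percentile of virus and worm probes gave 2 higher with SCF, 3 higher and 8 lower with imatinib, and 54 that differed between the cell types, and raised the correlation of the KIT effects to 0.50. Probes at least 1.5 times their mismatch probe gave 1 higher with SCF, 6 higher and 6 lower with imatinib, and a correlation of 0.36. This filter also dropped every miRNA without a mismatch probe, and only 282 of the 389 have one. Of the miRNAs higher with SCF, miR-471, miR-7*, miR-698 and miR-495 have none, so they were removed without being judged. The same holds for miR-689, miR-703, miR-466, miR-713 and miR-467a with imatinib. Under the other alternatives the correlation lay between 0.11 and 0.23.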

Other observations

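The correlation under a stricter detection and the mismatch value were chosen only after the results were seen. Marker miRNAs of other cell types were compared in the same way. The pluripotency markers, miR-290 to miR-295 and the miR-302 cluster, had a median log2 difference of 0.88 with imatinib in P815 over 6 listed members, which turned negative with no detection filter. Of the 6, 5 were listed only with imatinib, so the detection rule favours a positive value. Among these 5, miR-294 and miR-291a-3p were 2-fold higher, and these differences are open-ended. The mismatch probe of miR-294 differed by 1.67. With SCF their median was -0.05 over 8 members (percentile 55.9), 0.55 with detection on both arrays, with 1, miR-302b, 2-fold higher, and in P815 against BMMC it was -0.90 over 5 members, 4 of them listed only in BMMC, and above 0 with no detection filter. The stromal markers had a median of -0.22 with SCF over 5 members (percentile 2.87), with miR-145 at 0.74 and miR-10b at -0.64, and of -1.62 in P815 against BMMC over 3 members, 2 of them listed only in BMMC, above 0 with no detection filter. Their 1 listed member with imatinib, miR-214, lay at -0.33 and turned above 0 with median centring and without scaling. The epithelial markers had a median of 0.11 with SCF over 4 members (percentile 91.4), which turned negative without scaling and in the authors' values, and miR-200b lay at -0.60 with imatinib. Over 2 epithelial members the median in P815 against BMMC was 0.12, negative with median centring, cyclic loess and no scaling.

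Markers with fewer listed members are given as values. The muscle markers miR-1 and miR-206 were at least 2.05-fold and 2.08-fold higher in P815 than in BMMC, with a median of 1.11 that was -0.17 without scaling. miR-206 differed by -0.15 with SCF and by -0.60 with imatinib. The neural markers miR-128a and miR-128b were at least 2.69-fold and 2.49-fold higher in P815 and differed by 0.21 and 0.19 with imatinib, and the neural median with SCF was -0.09 over 3 members, 2 of them listed only without SCF. The erythroid miRNAs miR-144 and miR-486 lay at 0.08 and -0.22 with SCF, where their median of -0.07 turned with cyclic loess, and miR-144 at -0.75 with imatinib and at 0.73 in P815 against BMMC, the last negative without scaling. The liver miRNA miR-122a lay at 0.19 with SCF, -0.34 with imatinib and 0.92 in P815 against BMMC, and each of these signs turned without scaling, while the lymphoid miRNA miR-150 was not listed on any array. The 4 control probes for glycine tRNA went different ways with imatinib. One differed by -0.44 with SCF and by -0.69 with imatinib on the log2 scale, and the others by -0.19, -0.24 and -0.06 with SCF and by 0.14, 0.24 and 0.36 with imatinib.

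With detection above the 95th percentile of virus and worm probes, an alternative chosen after seeing the data, the KIT effects in BMMC and P815 correlated at r = 0.50 and rho = 0.32 across 47 miRNAs. Without the 2 miRNAs farthest from the median in BMMC, r was 0.33. These brighter miRNAs are not independent replicates, and with 1 array per group the value has no error.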
